A study of Rattus norvegicus with 9 samples.

How the data were processed

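Total RNA from the kidneys of 9 rats was hybridised to Affymetrix RAE230A arrays, per the file headers, 1 array per animal. RAE230A is a short-oligonucleotide array, on which a probe set is a group of short probes and a gene can have several probe sets. The deposited value table holds 1 intensity per probe set and array on a linear scale, from 0 upward. The deposited intensities had already been scaled between arrays, since the mean after trimming 2% of the probe sets at each end was 100.02 or 100.03 on every array. The software that summarised the probes, its background correction and any detection calls are not given in the sources used here. The deposited experiment files give each array's chip type, lot, fluidics station, protocol and run times, and were used to find batches. All 9 arrays shared 1 chip type, 1 lot, 1 station, 1 protocol and 1 day, and fell into 3 fluidics runs, told apart by start times at least 10 minutes apart. Groups came from the labels, which name each animal as case or control. Animals are separate samples with no pairing between groups.

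The table holds 15923 probe sets. The 57 control probe sets were left out, and gene symbols came from the platform annotation, checked against a RefSeq gene table of the GRCr8 assembly by Entrez ID. Of the 15866 other probe sets, 12783 had 1 symbol, 312 several and 2771 none, and 12748 of those with 1 symbol were matched. No coordinates are given, because the annotation of the array names no build. Probe sets with several symbols or none were tested but are not named.

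Values were used as log2(signal + 5.03), where the pseudocount is 10% of the table's median signal of 50.3, so that log2 differences understate the change of dim genes. No further normalization was applied. Probe sets were kept when their mean log2 value over the 9 arrays lay above the 40th percentile, a level near a signal of 33.3, which left 9519. Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All differences are case minus control.

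For gene lists, each gene was represented by its brightest probe set with a single symbol, which gave 7147 genes. The 34 lists had been written before the data were examined, and the 29 with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry, and adjusted over the lists. They covered immediate early, hypoxia-inducible, tubular injury, angiotensin and aldosterone, heat shock, unfolded protein response, inflammatory, interferon, fatty acid oxidation, gluconeogenesis, oxidative phosphorylation, oxidative stress, cytochrome P450, vasoactive, p53, proliferation, circadian, glucocorticoid-responsive, cholesterol, extracellular matrix and ribosomal protein genes. They also covered markers of proximal tubule, loop of Henle and distal tubule, collecting duct, osmolytes and medulla, podocytes, endothelium, smooth muscle and mesangium, leukocytes, blood cells, adrenal cortex, adipose tissue, skeletal muscle and liver. A per-animal list score was the mean log2 value of a list's genes minus the mean of all represented genes, compared by exact permutation over all 126 splits of the 9 animals. After adjustment over the 29 lists the smallest exact permutation p was 0.132.

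Genes were named by a rule fixed before the data were examined. It took up to 12 genes in each direction past the threshold, or, where fewer than 8 passed, the 8 with the smallest p. It added up to 4 genes with the smallest p in each list, and always Agt, Ace, Agtr1a, Havcr1, Lcn2, Hmox1 and Fos where measured, and 1 further gene that is not reported here. Not every gene the rule allows is named in the text.

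Alternatives covered the pseudocount (1% and 50% of the median), the filter (none and the 60th percentile), quantile normalization, median centring, eBayes without a trend, array weights, all probe sets of a list's genes, and leaving out each animal in turn. A further 4 settings were added after the data had been seen, namely the fluidics run as a block, the log2 actin 3'/5' ratio as a covariate, and 2 sets of animals left out. Blocks by chip lot, station or date were not possible with 1 value each.

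The steps were tested on simulated data with the real intensities and spreads, in 10 simulations with 200 changed probe sets among 9519. Calls were made for 19.1% of probe sets changed by 0.5 on the log2 scale, 78.4% of those changed by 1 and 97.4% of those changed by 2, and 6.3% of calls were false. A list shifted by 0.2 was called in 10 of 10 simulations. The probe sets were simulated independently of each other, so the list test was not tried on correlated genes. Other lists were called 0.1 times per simulation, against a median of 3 lists in other splits of the real arrays. Tables were prepared with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.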

Results

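Gene expression was measured in the kidney of 9 rats, 4 labelled case and 5 labelled control, with 1 array of total RNA per animal. The series concerns gene expression in low blood pressure, and the labels do not say how the case animals were treated, so the groups are called case and control throughout. Each array gave 1 signal for each of 15923 probe sets, and the median signal per array lay between 45.2 and 55.6. The correlation of log2 signals between arrays lay between 0.89 and 0.97, so no 2 arrays were copies of each other. The number of animals limits the precision of every difference. The comparison asked which genes and gene groups differed between case and control kidneys.

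Gene lists for oxidative stress defence, drug and arachidonate metabolism, glucocorticoid response, fatty acid oxidation and glucose production rose in the case kidneys, and of these only the oxidative stress call held with an estimated correlation between genes (adjusted p = 0.0422, against 0.150 to 0.218 for the other 4). Lists for interferon response, extracellular matrix and 2 vascular cell types fell, and these 4 calls were lost with an estimated correlation (adjusted p = 0.218 to 0.453) and with a measure of RNA shortening as a covariate. No list passed limma's fry test of a shift one way or exact permutation over animals after adjustment (smallest adjusted p = 0.0686 and 0.132). In 5 of 100 splits of the arrays, the real one included, as many lists were called, so chance cannot be excluded for their number. The shifts of the 5 lists named as higher were small, between 0.14 and 0.28 on the log2 scale. The genes with the smallest p among those higher in case were Por, which passes electrons to microsomal cytochrome P450 enzymes, and Igfbp1, which binds insulin-like growth factors. Por signal at the named probe set was 337 ± 66.1 (SD, n = 4) in case and 177 ± 33.5 (SD, n = 5) in control (limma adjusted p = 0.255). The other Por probe set tested showed a log2 difference of only 0.01 ± 0.20 (SE).

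No single gene passed the test. Of 9519 probe sets tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.136. At an unadjusted p under 0.05 there were 637 probe sets, 274 higher and 363 lower in case, where chance alone would give 476. The values of the 4 case and 5 control animals did not overlap at all for 93 probe sets higher and 86 lower in case, against 151 in both directions together that chance gives (1.59% of those tested). Leaving out case animal 5 raised the count past the threshold to 53, with 14 higher and 39 lower. Leaving out case animal 3, 7 or 8 gave a count of 1, a probe set of Pheta1 that otherwise lay below the filter. Of the 12 list calls made by camera, 11 were lost with an estimated correlation. The camera p also rose where the estimate lay below the preset 0.01, for the oxidative stress list (-0.002) and the smooth muscle list (-0.04). The 2 forms of camera therefore differ in more than the correlation. With limma's fry, which tests whether a list's genes moved one way on balance, no list passed, and the smallest adjusted p was 0.0686, for the oxidative stress list. Its test of change in either direction passed for the glucocorticoid, oxidative stress and unfolded protein response lists (adjusted p = 0.0141 for each) and for the P450 list (0.0374).

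The 8 named genes with higher values in case, none past the threshold, had differences from 0.49 to 1.03. Igfbp1 signal was 483 ± 135 (SD, n = 4) in case and 232 ± 53.1 (SD, n = 5) in control, a log2 difference of 1.03 ± 0.19 (SE). The log2 difference of Por was 0.92 ± 0.16 (SE), with limma adjusted p = 0.255 for both genes. Xdh, the enzyme that forms uric acid, was higher by 0.78 ± 0.15, and Slc17a3, a transporter of organic anions such as urate, by 0.76 ± 0.16. Akr1b8, an aldo-keto reductase, was higher by 0.79 ± 0.15. Tsc22d3, a classical glucocorticoid-induced gene, was higher by 0.60 ± 0.13, Pfkfb4, a regulator of glycolysis, by 0.66 ± 0.14, and Tmem140 by 0.49 ± 0.11. A further Por probe set showed a log2 difference of only 0.01 ± 0.20, so the difference of this gene rested on 1 of its 2 tested probe sets.

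The 8 named genes with lower values in case, again none past the threshold, had differences from -0.62 to -1.91. Nherf1, a scaffold for transporters of the brush border, had a log2 difference of -1.91 ± 0.45 (SE), with signals of 21.5 ± 24.2 (SD, n = 4) in case and 73.5 ± 23.3 (SD, n = 5) in control. Its other probe set differed by -0.22 ± 0.11. St6gal1, a sialyltransferase, differed by -1.16 ± 0.28 at the named probe set and by -0.18 ± 0.32 at another. Mplkip differed by -0.93 ± 0.17 and Oacyl by -0.89 ± 0.16. Mxi1, an antagonist of MYC, differed by -0.92 ± 0.21, and Marcks, a substrate of protein kinase C, by -0.82 ± 0.19, and the other probe set of each was also lower in case, by -0.49 ± 0.15 and -0.60 ± 0.25. Sox4, a transcription factor, differed by -0.85 ± 0.19, but its other probe set by -0.09 ± 0.25. Sorl1, a sorting receptor, differed by -0.62 ± 0.15, with its 3 other probe sets between -0.28 and -0.62.

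The arrays were washed in 3 fluidics runs on 1 day. Run 1 held 3 case animals and 1 control, run 2 held 1 case animal and 3 controls, and run 3 held 1 control. All 16 genes named so far kept the sign of their difference with the run as a block and within each of runs 1 and 2. They were chosen by the smallest p on these same arrays. For 14 of them the case and control values did not overlap, so the sign could not change within a run. The kept signs therefore do not test the run as a cause. Por differed by 0.89 with the run as a block, 0.84 within run 1 and 0.93 within run 2. St6gal1 differed by -0.97 with the block, but by -0.15 within run 1 and -1.80 within run 2.

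**Figure D1:**
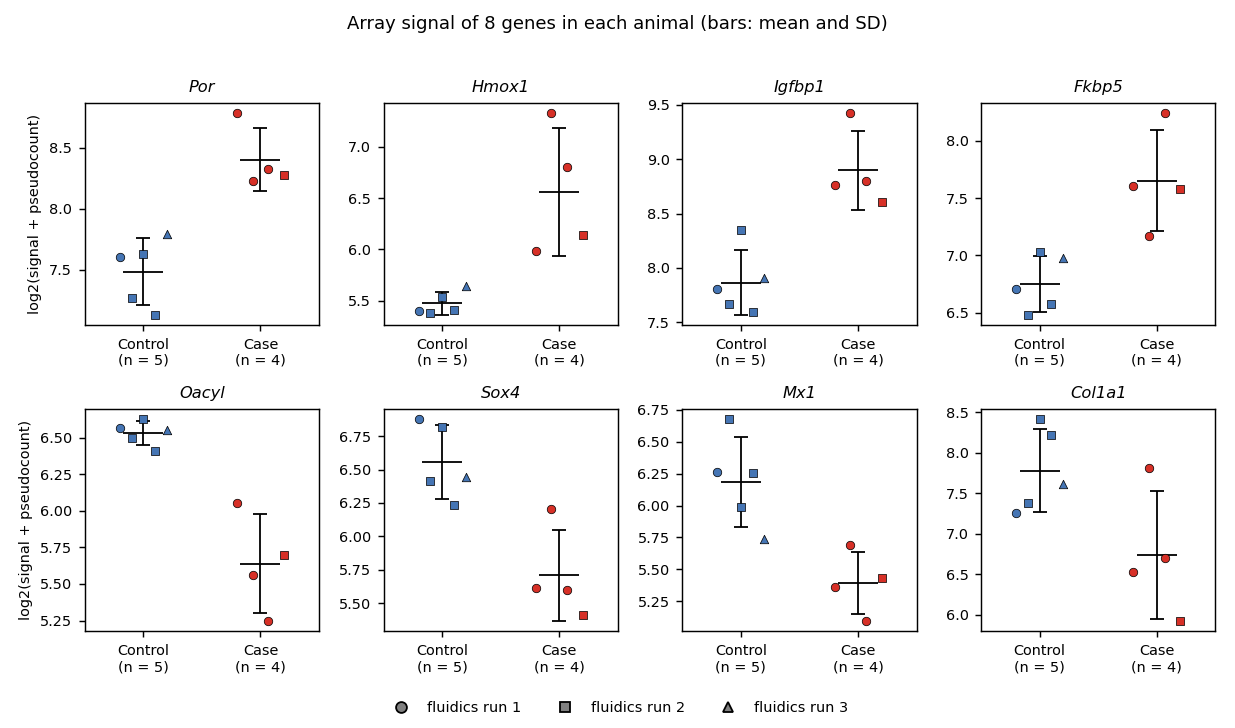
Array signal of 8 genes in each animal, as log2 of the signal plus a pseudocount of 5.03 on the vertical axis, with control animals in blue, case animals in red, a symbol shape for each fluidics run, and bars for the mean and SD of 5 control and 4 case animals. Por, Hmox1, Igfbp1 and Fkbp5 lay higher in every case animal than in any control, and Oacyl, Sox4 and Mx1 lay lower, while Col1a1 overlapped.

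Genes of oxidative stress defence and detoxification rose together in case. Over the 28 genes measured, the mean log2 difference was 0.21, and 20 of them lay above 0 (camera adjusted p = 0.000102, adjusted p = 0.0422 with an estimated correlation, and fry adjusted p = 0.0686). No member passed over all probe sets, and 7 were higher when adjusted over the list alone. Hmox1, which degrades heme, was higher by 1.09 ± 0.24 (SE), with signals of 96.5 ± 45.0 (SD, n = 4) and 39.5 ± 3.58 (SD, n = 5). Gstp1, a glutathione transferase, was higher by 0.75 ± 0.19, Txnrd1, a thioredoxin reductase, by 0.53 ± 0.15, and Mt2A, a metallothionein, by 0.63 ± 0.18. Another Txnrd1 probe set differed by only 0.14 ± 0.24. The list score, the mean of the members minus that of all genes, was 0.22 higher in case, above every control in every case animal (exact permutation p = 0.00794, 2-sided, the smallest that 126 splits allow). Adjusted over the 29 lists this exact permutation p was 0.132, and 0 lists passed by permutation after adjustment. With the fluidics run as a block the score difference was 0.22, with 0.19 within run 1 and 0.25 within run 2. Since the groups did not overlap in this score, its sign could not change within a run.

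The list of xenobiotic and arachidonate cytochrome P450 genes also rose, by a mean of 0.26 over 14 genes, 11 of them above 0 (camera adjusted p = 0.000202). Its call was lost with an estimated correlation (adjusted p = 0.218). Adjusted over the list alone, 2 members were higher and 0 lower, namely Por and Sult1a1, a sulfotransferase that differed by 0.75 ± 0.19. The other Por probe set, which does not represent the gene in the list, differed by 0.01 ± 0.20. Cyp4f1 differed by 0.33 ± 0.15 and Cyp2e1 by 0.30 ± 0.15. The score difference was 0.27 (exact permutation p = 0.0317), and 0.30 with the run as a block, 0.27 within run 1 and 0.32 within run 2. The 95% interval of the blocked difference, -0.09 to 0.69, includes 0. So does the interval with the log2 actin 3'/5' ratio as a covariate, -0.03 to 0.61. Without case animal 3 the mean was 0.16, and the list was still called (adjusted p = 0.0392).

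Glucocorticoid-responsive genes rose by a mean of 0.28 over 18 genes, 13 of them above 0 (camera adjusted p = 9.2e-05). With an estimated correlation the call was lost (adjusted p = 0.150). Adjusted over the list alone, 4 members were higher and 0 lower. They were Tsc22d3, Sult1a1, Mt2A and Fkbp5, a co-chaperone of the glucocorticoid receptor that differed by 0.90 ± 0.20 (SE), with signals of 203 ± 67.1 (SD, n = 4) and 104 ± 18.5 (SD, n = 5). The score difference of the list was 0.29 (exact permutation p = 0.0238), and 0.23 with the run as a block, 0.13 within run 1 and 0.33 within run 2.

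Genes of fuel metabolism rose as well. The fatty acid oxidation and peroxisomal list rose by a mean of 0.14 over 31 genes, 23 of them above 0 (camera adjusted p = 0.000202, and adjusted p = 0.150 with an estimated correlation). No member passed when adjusted over the list alone, where Eci1 differed by 0.53 ± 0.14, Phyh by 0.48 ± 0.16, and Cpt1a and Cpt2, the carnitine palmitoyltransferases, by 0.55 ± 0.20 and 0.48 ± 0.19. A second Cpt1a probe set went the other way, by -0.31 ± 0.19. Without case animal 3 the mean of the list was 0.09, and it was still called (adjusted p = 0.0228). The list of gluconeogenesis and glucose handling rose by a mean of 0.20 over 13 genes, 10 of them above 0 (camera adjusted p = 0.00181, and adjusted p = 0.150 with an estimated correlation), with 0 members past the list alone. Pck1, which commits carbon to glucose production, differed by 0.49 ± 0.22, the glucose transporter gene Slc2a2 by 0.53 ± 0.20, and the aspartate aminotransferases Got1 and Got2 by 0.35 ± 0.15 and 0.26 ± 0.11. The score differences of the fatty acid and glucose lists were 0.16 and 0.21 (exact permutation p = 0.0238 for each). With the run as a block they were 0.17 and 0.25, within run 1 0.19 and 0.27, and within run 2 0.14 and 0.24. The 95% interval of the blocked fatty acid difference, -0.02 to 0.35, includes 0, and that of the blocked glucose difference, 0.08 to 0.42, does not. The 5 lists described so far held 97 genes, 7 of them in more than 1 list.

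Interferon and matrix genes fell. The interferon and antigen presentation list fell by 0.20 on average over 18 genes, 4 of them above 0 (camera adjusted p = 0.00172, and adjusted p = 0.453 with an estimated correlation). Adjusted over the list alone, 1 member was lower, Mx1, an interferon-induced GTPase, with a log2 difference of -0.79 ± 0.20 (SE). Usp18 differed by -0.47 ± 0.16, Psmb9, an immunoproteasome subunit, by -0.65 ± 0.23, and Mx2 by -0.53 ± 0.20. The extracellular matrix and fibrosis list fell by 0.19 on average over 27 genes, 6 of them above 0 (camera adjusted p = 0.00249, and adjusted p = 0.453 with an estimated correlation), with 0 members past the list alone. Col1a1 differed by -1.04 ± 0.34, Col1a2 by -0.47 ± 0.23 and Spp1, which encodes osteopontin, by -0.59 ± 0.29, while Lox, which crosslinks collagen, was higher by 0.52 ± 0.21. The other probe sets of Col1a1 and Col1a2 differed by -0.52 ± 0.14 and -0.20 ± 0.17. Over all animals the scores of the interferon and matrix lists differed by -0.19 and -0.17 (exact permutation p = 0.190 and 0.119). Within run 1 these scores differed by -0.41 and -0.07, within run 2 by -0.19 and -0.44, and with the run as a block by -0.30 and -0.25. Without case animal 7 the interferon list differed by -0.10 (adjusted p = 0.116), and without case animal 8 the matrix list differed by -0.12 (adjusted p = 0.0997), so each call was lost. Both calls were also lost with the actin 3'/5' ratio as a covariate, without case animals 7 and 8 (means -0.01 and -0.05, adjusted p = 0.734 for each) and without case animal 7 and control animal 4 (means -0.04 and -0.16, adjusted p = 0.652 and 0.0703), and the interferon call with the filter at the 60th percentile (mean -0.07, adjusted p = 0.273).

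Markers of vessel cells were lower. Smooth muscle and mesangial markers fell by 0.16 on average over 11 genes, 1 of them above 0 (camera adjusted p = 0.0427, and adjusted p = 0.218 with an estimated correlation). Endothelial markers fell by 0.16 on average over 11 genes, 3 of them above 0 (camera adjusted p = 0.0457, and adjusted p = 0.453 with an estimated correlation). No member of either passed adjusted over the list alone. Exact permutation p of the list scores was 0.0317 for smooth muscle and 0.175 for endothelium. Myh11, the smooth muscle myosin heavy chain, differed by -0.43 ± 0.14, Rgs5 by -0.38 ± 0.18 and Des by -0.40 ± 0.21, and the endothelial genes Esam and Egfl7 by -0.48 ± 0.19 and -0.45 ± 0.18, with another Egfl7 probe set at -0.17 ± 0.17. The scores of the 2 lists differed by -0.17 and -0.22 with the run as a block, by -0.11 and -0.31 within run 1 and by -0.23 and -0.14 within run 2, and the smooth muscle call was lost with the block (camera adjusted p = 0.0570). Leaving out control animals 4 or 9 or case animals 3, 7 or 8 ended both calls, and control animals 10 or 11 that of smooth muscle, with the means between -0.11 and -0.17 and the adjusted p between 0.0510 and 0.204. With the actin 3'/5' ratio as a covariate both calls were lost (adjusted p = 0.167 for smooth muscle and 0.203 for endothelium), as they were with no filter (0.224 and 0.0627), with quantile normalization (0.106 and 0.0590), without case animals 7 and 8 (0.260 and 0.609) and without case animal 7 and control animal 4 (0.109 and 0.561). The smooth muscle call was lost with the filter at the 60th percentile (0.206), and the endothelial call without an intensity trend (0.0531) and with array weights (0.0647), with all these means between -0.06 and -0.19. Without case animal 5 the endothelial list differed by -0.26 and was still called. The 95% interval of the smooth muscle score difference was -0.20 to -0.01 with the actin ratio and -0.31 to -0.03 with the run as a block. Neither includes 0. Those of the endothelial score, -0.39 to 0.17 and -0.56 to 0.12, both include 0.

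Heat shock and chaperone genes fell by 0.27 on average over 12 genes, 2 of them above 0, just past the threshold (camera adjusted p = 0.0495, and adjusted p = 0.453 with an estimated correlation), with 0 members past the list alone. Serpinh1, a collagen chaperone, differed by -0.96 ± 0.34, Hsph1 by -0.80 ± 0.36 and Hsp90ab1 by -0.33 ± 0.16 (-0.87 ± 0.30 at another probe set), while Bag3 was higher by 0.27 ± 0.11. Control animal 10 had an Hsph1 signal of 1150, where the highest other animal had 441, and a Serpinh1 signal of 748 against 270. Without this animal Hsph1 differed by -0.42 and Serpinh1 by -0.61. Without control animal 10 the list differed by -0.14 and the call was lost (adjusted p = 0.167). It was also lost without control animals 9 or 11 (adjusted p = 0.114 and 0.0978) or case animals 3, 5, 7 or 8 (0.0773, 0.209, 0.116 and 0.0541), with the actin 3'/5' ratio as a covariate (0.210) and with the run as a block (0.415). A pseudocount of 1% of the median (0.0504), no filter (0.252), no intensity trend (0.0693), array weights (0.0679) and leaving out case animals 7 and 8 (0.121) ended it too, with a mean of -0.21 with no filter and between -0.27 and -0.28 in the others. With the actin ratio and with the run the means were -0.18 and -0.20. The list score differed by 0.05 within run 1 and by -0.40 within run 2, and by -0.18 with the run as a block. Over all animals the exact permutation p of the score was 0.214.

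Genes of protein synthesis and respiration were higher by small amounts. Ribosomal protein genes rose by 0.06 on average over 42 genes, 31 of them above 0 (camera adjusted p = 0.0336, and adjusted p = 0.558 with an estimated correlation). Oxidative phosphorylation genes rose by 0.06 over 38 genes, 27 of them above 0 (camera adjusted p = 0.0336, and adjusted p = 0.481 with an estimated correlation). No member of either passed adjusted over the list alone, and Rpl35 differed by 0.20 ± 0.11, Cyc1 by 0.31 ± 0.11 and Sdhb by 0.20 ± 0.12. With the run as a block the scores differed by 0.16 and 0.14, within run 1 by 0.13 and 0.06 and within run 2 by 0.18 and 0.22. Over all animals the exact permutation p of the ribosomal and respiratory scores was 0.198 and 0.151. With quantile normalization the means were 0.02 for each (adjusted p = 0.920 and 0.638), so both calls were lost. Without case animal 8 the means were also 0.02 (adjusted p = 0.389 for each), and both calls were lost too without control animals 4 or 11, the ribosomal one without case animal 5 and the respiratory one without control animal 9, with adjusted p between 0.0609 and 0.246. With the actin 3'/5' ratio as a covariate the means were 0.07 for ribosomal and 0.06 for respiratory genes, about as large as without it, but both calls were lost (adjusted p = 0.0779 and 0.154). The same was seen with the filter at the 60th percentile (means 0.07 and 0.06, adjusted p = 0.0982 and 0.124). Both calls were also lost without case animals 7 and 8 (means 0.06 and 0.04, adjusted p = 0.177 and 0.437), and the ribosomal call without case animal 7 and control animal 4 (mean 0.08, adjusted p = 0.0600). Without case animal 7 alone the ribosomal mean was 0.10, and the list was still called.

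**Figure D2:**
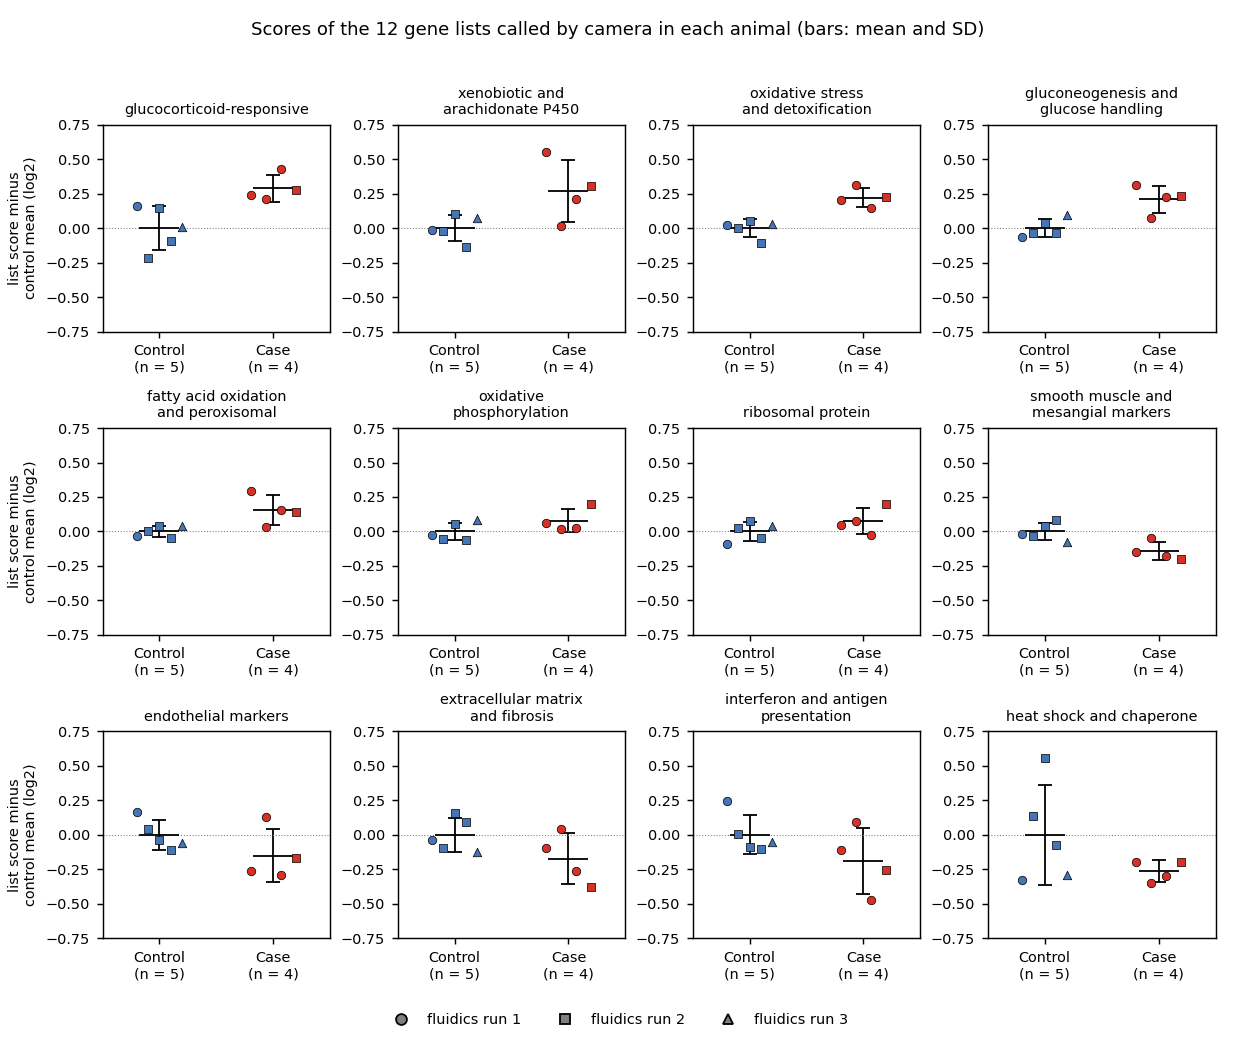
Scores of the 12 gene lists called by camera in each animal, as the mean log2 signal of a list's genes minus that of all genes, set to 0 at the control mean, with control animals in blue, case animals in red, a symbol shape for each fluidics run, and bars for the mean and SD of 5 control and 4 case animals. The oxidative stress score lay 0.22 higher in case with no overlap, while control animal 10 stood alone at the top of the heat shock panel.

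No list of blood pressure control genes was called. The 95% intervals of the score differences were -0.14 to 0.08 for the angiotensin and aldosterone list and -0.16 to 0.09 for the vasoactive list. The angiotensin and aldosterone list had a mean difference of -0.04 over 9 genes (camera adjusted p = 0.890). Agt, which encodes angiotensinogen, differed by 0.01 ± 0.22, Agtr1a, an angiotensin II receptor, by -0.35 ± 0.21 (-0.13 without case animal 3, and -0.35 ± 0.16 at another probe set), and Enpep, an aminopeptidase that cleaves angiotensin II, by 0.42 ± 0.15, while a second Enpep probe set differed by -0.03 ± 0.18. Sgk1, a kinase that acts on the epithelial sodium channel and is also in the glucocorticoid list, differed by 0.34 ± 0.18, with -0.13 within run 1 and 0.77 within run 2, and Agtrap, which binds an angiotensin II receptor, by -0.29 ± 0.21. Ace lay below the signal filter, with signals of 21.7 ± 6.21 (SD, n = 4) in case and 22.8 ± 11.0 (SD, n = 5) in control at its brighter probe set. The list of vasoactive peptide, nitric oxide and adrenergic genes had a mean of -0.05 over 14 genes (adjusted p = 0.774).

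Markers of injury and stress were mixed. Tubular injury markers had a mean difference of 0.02 over 16 genes (camera adjusted p = 0.864), with Sox4 lower and 0 higher when adjusted over the list alone. Krt8 differed by 0.41 ± 0.13, Lcn2 by -0.21 ± 0.23, and Havcr1, below the filter, had signals of 26.6 ± 11.2 (SD, n = 4) and 27.0 ± 10.9 (SD, n = 5). Lcn2 changed sign in 3 of the alternative settings, to 0.17 without case animals 7 and 8. Hypoxia-inducible genes had a mean of 0.07 over 25 genes (adjusted p = 0.186), with Pfkfb4 higher when adjusted over the list alone, Bnip3 at 0.54 ± 0.21, Epas1 at 0.37 ± 0.13 and Ndrg1 at 0.31 ± 0.11. Another Epas1 probe set differed by -0.09 ± 0.30. The score of the hypoxia list differed by 0.08 (exact permutation p = 0.0317, the same as for the P450 list). The unfolded protein response list had a mean of 0.01 over 14 genes (adjusted p = 0.985) but members that went both ways (adjusted p = 0.0141 in limma's fry test of change in either direction). Adjusted over the list alone, Herpud1 and Ddit3, a transcription factor of stressed cells, were higher, by 0.50 ± 0.14 and 0.53 ± 0.16, while the chaperones Pdia4 and Hspa5 differed by -0.40 ± 0.16 and -0.31 ± 0.13.

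Inflammatory cytokine and adhesion genes had a mean of -0.11 over 14 genes (camera adjusted p = 0.239), with the chemokine genes Cxcl10 at -0.48 ± 0.15 and Ccl4 at -0.67 ± 0.22. Without case animal 5 the list differed by -0.23 and was called (adjusted p = 0.0245). Immediate early genes had a mean of -0.02 over 14 genes (adjusted p = 0.848), with Egr1 at -0.41 ± 0.21 and Ccn2 at 0.54 ± 0.25. Fos lay below the filter, with signals of 30.1 ± 15.1 (SD, n = 4) and 34.7 ± 12.6 (SD, n = 5). Cholesterol and lipid synthesis genes had a mean of -0.07 over 20 genes (adjusted p = 0.436), and Scd, a fatty acid desaturase, differed by -1.24 ± 0.58. The p53 and cell cycle arrest list had a mean of 0.11 over 8 genes (adjusted p = 0.281), proliferation genes -0.10 over 14 (adjusted p = 0.238) and circadian genes 0.07 over 11 (adjusted p = 0.308). The p53 list was called without case animal 3 (mean 0.20, adjusted p = 0.0465), and proliferation genes were called when all probe sets of the list's genes were used (mean -0.16, adjusted p = 0.0340).

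No list of tubule segment markers was called, but the 95% intervals of the score differences allow shifts either way. They ran from -0.10 to 0.19 for proximal tubule and from -0.14 to 0.19 for loop of Henle and distal tubule. For collecting duct the interval ran from -0.33 to 0.25. Proximal tubule markers had a mean of 0.04 over 28 genes (camera adjusted p = 0.477), although their median was -0.02. Markers of the loop of Henle and distal tubule had a mean of 0.01 over 12 genes (adjusted p = 0.864), with a median of -0.01, and collecting duct markers -0.05 over 14 (adjusted p = 0.504). Of the collecting duct genes, Scnn1a, a subunit of the epithelial sodium channel that is also in the glucocorticoid list, differed by 0.61 ± 0.22, with -0.03 within run 1 and 1.44 within run 2. Slc26a4 differed by 0.37 ± 0.19, Avpr2, the vasopressin receptor of the collecting duct, by -0.28 ± 0.16 and Fxyd4 by -0.36 ± 0.21. Osmolyte and medulla genes had a mean of -0.10 over 7 genes (adjusted p = 0.239), with Akr1b1, the aldose reductase that makes sorbitol, at -0.44 ± 0.14 and Slc6a6, the taurine transporter, at -0.42 ± 0.16 (-0.97 ± 0.39 at another probe set). With all probe sets of its genes the osmolyte list differed by -0.27 and was called (adjusted p = 0.0231). Podocyte markers had a mean of 0.01 over 7 genes (adjusted p = 0.864), and leukocyte markers -0.09 over 15 (adjusted p = 0.354), with Ctss higher by 0.48 ± 0.18. With the fluidics run as a block the leukocyte list differed by -0.25 and was called (adjusted p = 0.00742), as it was without case animal 5 (mean -0.18, adjusted p = 0.0420). Too few genes were measured to test blood cell markers (4 genes, mean -0.10), liver markers (4, mean 0.06), adrenal cortex markers (2, mean -0.13), skeletal muscle markers (2, mean -0.03) and adipose markers (1, difference 0.11).

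The ratio of 3' to 5' signal of the actin control probe sets, which is higher where RNA is shortened, was 2.31 ± 0.886 (SD, n = 4) in case and 1.69 ± 0.349 (SD, n = 5) in control (exact permutation p = 0.246, 2-sided). Case animals 7 and 8 had the highest ratios, 3.05 and 3.11. The GAPDH ratio was 1.99 ± 0.351 and 1.66 ± 0.104 (exact permutation p = 0.0873), and the median signal 48.3 ± 2.71 and 51.6 ± 2.42 (exact permutation p = 0.0952). With the log2 actin ratio as a covariate, the oxidative stress score still differed by 0.25 and the glucocorticoid score by 0.30, whereas the matrix score differed by -0.05 and the interferon score by -0.10, and their calls were lost (camera adjusted p = 0.489 and 0.149). The endothelial, smooth muscle, heat shock, ribosomal and oxidative phosphorylation calls were lost as well, with means of -0.11, -0.11, -0.18, 0.07 and 0.06, against -0.16, -0.16, -0.27, 0.06 and 0.06 without the covariate. This left 5 of the 12 lists called. The first principal component held 33.2% of the variance and ran from control animal 4 to case animal 7.

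Leaving out 1 animal moved the difference of further genes named above by over 1.5 times. Without case animal 3, Phyh differed by 0.31 and Lox by 0.34. Without case animal 7, Ccl4 differed by -0.42, Slc2a2 by 0.32 and Ccn2 by 0.30. Without case animal 8, Scnn1a differed by 0.38, Col1a2 by -0.28, Des by -0.25, and Rpl35 and Sdhb by 0.13 each. Without control animal 11, Pck1 differed by 0.31. Lcn2 differed by -0.41 without case animal 3 and by -0.03 without case animal 7, and Agt lay between -0.15 and 0.14 over all single animals left out.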

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

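In 8 results, 1 animal lay far from the rest of its group, by the gap to its nearest neighbour over the range of the group. About 1 in 20 groups does so by chance, and 228 groups were examined, so that 11.4 would be met by chance alone. Case animal 5 gave 5 of the 8. It was lowest for Cpt1a (0.863 of the range), and highest for Gstp1 (0.850), Scd (0.868), Serpinh1 (0.856) and the score of the inflammatory cytokine and adhesion list (0.858). Its Scd value was 6.89 on the log2 scale against at most 4.59 in the other case animals. Case animal 3 was lowest for Agtr1a (0.885) and highest for Eci1 (0.918). Control animal 10 was highest for Serpinh1 (0.718), at 9.56 against at most 8.11 in the other controls.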

How the results depend on the processing

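The settings that block the fluidics run, add the actin ratio, or leave out a pair of animals were chosen after the data had been seen. Of 0 probe sets past the threshold, 1 appeared with a pseudocount of 50% of the median and 1 with no filter, the Pheta1 probe set both times, lower in case. At an unadjusted p the count of 637 became 988 with no filter, where more probe sets were tested, and 285 without case animals 7 and 8, where fewer animals were left. Leaving out single animals gave 0 to 53 changed probe sets, 0 to 14 higher, 0 to 39 lower, and 423 to 1064 at an unadjusted p. The 53 came without case animal 5, and 47 of them had an unadjusted p under 0.05 with all animals. The 12 called lists became 1 with an estimated correlation, 5 with the actin ratio as a covariate, 5 without case animals 7 and 8, 7 without case animal 7 and control animal 4, and 6 to 12 without single animals, with 6 without case animal 8. The cause of these changes was not tested, apart from the numbers of probe sets and animals. The oxidative stress list was called in all 23 settings, with means between 0.18 and 0.25. The glucocorticoid, P450, fatty acid and gluconeogenesis lists were each called in every setting but the estimated correlation. Over 79 named genes no difference turned sign past a threshold, 7 values near 0 changed sign, and 10 passed the threshold, all without case animal 5. Over the 29 lists, 77 results lost a call, 6 gained one and 0 were reversed. The table gives no background or detection calls, so how far dim signals stand above background is unknown. No paired analysis was possible because the labels number the animals once over both groups.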

Other observations

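The tests with the fluidics run, the marker comparisons, the 3 further gene lists and the comparison of Pheta1 probe sets were chosen after the results they bear on had been seen. The actin covariate was added after the data had been seen, and its tests were set out before they were run.

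A list of further targets of NRF2, the transcription factor of antioxidant genes, was written once the oxidative stress result was known and shares no gene with that list. Its score was 0.15 higher in case (0.1462, exact permutation p = 0.0317, adjusted p = 0.0476 over the 3 further lists), with 19 of 28 genes above 0. The planned P450 list had the same exact permutation p, and an adjusted p of 0.132 over the 29 lists. The adjustment over 3 lists is therefore milder than that of the planned lists. The further list was also tried on the same 9 animals that prompted it, so it is no independent test. The genes named here were chosen after their values were seen. Gstm4, a glutathione transferase, was higher by 0.76 ± 0.23 (SE), Mgst1 by 0.52 ± 0.18 and Sqstm1, a selective autophagy receptor, by 0.36 ± 0.13. Without case animal 5, Sqstm1 differed by 0.22. Abcc1 differed by -0.45 ± 0.16 and Gsr, glutathione reductase, by -0.51 ± 0.30. No member passed the threshold over all probe sets. These values are consistent with the hypothesis of higher NRF2 activity in case kidneys, which these arrays do not measure and NRF2 protein in kidney nuclei would test.

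Genes of amino acid breakdown had a score 0.0889 higher in case (exact permutation p = 0.0159, adjusted p = 0.0476 over the 3 further lists), with 23 of 36 genes above 0 and members that went both ways. The planned oxidative stress list, with a smaller exact permutation p of 0.00794, had an adjusted p of 0.132 over the 29 lists. At an unadjusted p under 0.05, 1 member was higher, Aass, which breaks down lysine, by 0.43 ± 0.14, and 2 were lower, Acadsb by -0.53 ± 0.20 and Gatm by -0.34 ± 0.14. A list of genes raised by FoxO factors or fasting differed by 0.0252 (exact permutation p = 0.635), with a 95% interval from -0.10 to 0.15. The hypothesis that fasting separated the groups was therefore neither borne out nor excluded.

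The oxidative stress and glucocorticoid lists were higher in case by 0.22 and 0.29 as scores. The tables argue against the run and shortened RNA, as the actin ratio measures it, as whole causes of the oxidative stress shift. The difference was 0.2197 with the fluidics run as a block (95% interval 0.06 to 0.38) and 0.2473 with the actin ratio as a covariate (0.13 to 0.36). The blocked value rests on 1 control in run 1 and 1 case animal in run 2. The GAPDH ratio was 2.09, 2.39 and 1.93 in case animals 3, 7 and 8, 1.55 in case animal 5 and at most 1.79 in control. It was not used as a covariate, so shortening that only this ratio shows stays open. The glucocorticoid shift was 0.2964 with the actin ratio (0.02 to 0.57). With the run as a block it was 0.2327, and the interval over animals, from -0.08 to 0.55, includes 0, so the run was not excluded. The list was still called with the block (camera adjusted p = 0.00999). That call used the preset correlation of 0.01, where the estimated one was 0.11, so it does not decide about the run. Proximal tubule markers differed by 0.0491, with an upper bound of 0.19, but of 0.24 with the run as a block, above the blocked difference of either list, so a larger share of proximal tubule stays open for both. A difference between case and control animals remains a hypothesis found and examined on the same data.

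The matrix, endothelial and interferon scores were lower in case by 0.17 on average, a difference of -0.171. With the actin ratio as a covariate their mean difference was -0.0871 (95% interval -0.28 to 0.10), so shortened RNA cannot be excluded. With the run as a block the difference was larger, -0.2585, where the run as its cause would make it smaller. The 3 lists were still called (camera adjusted p = 0.000340 for the matrix and interferon lists and 0.0142 for the endothelial list). Those calls used the preset correlation of 0.01, where the estimated ones were 0.20 to 0.30, so they do not decide about the run. The interval over animals was -0.55 to 0.03 with the block, and those of the 3 scores without it also include 0, so these intervals do not exclude the run. Smooth muscle markers differed by -0.1428 (-0.25 to -0.04), and leukocyte markers by -0.08 (-0.39 to 0.24), so a smaller share of vessels and interstitium in the case pieces cannot be told apart from lower expression, and a true difference between case and control, which the design names, stays open as well.

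The clearest separation on the arrays was a probe set of Pheta1, singled out after its values were seen. Its signals were 10.1 to 13.2 in case and 51.7 to 95.3 in control, a log2 difference of -2.05 ± 0.21 (SE, limma adjusted p = 0.00841 with no filter, and 0.00470 to 0.0132 over the other settings that called it, where a pseudocount of 50% of the median gave -1.28), although its mean lay below the filter. A change of the whole transcript is argued against, since another Pheta1 probe set above the filter differed by -0.07 (95% interval -0.38 to 0.24). A further dim Pheta1 probe set, also below the filter, differed by 0.70. Sequence differences between the animals of the groups, such as 2 stocks of rats, could lower 1 probe set alone, but 21 of the 126 splits of the arrays gave at least 1 probe set with a gap over 1 between groups (1 in the real split, at most 3 in others), so this stays open. A different end of the transcript in case kidneys also stays open and was not tested.

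The split of the 9 arrays into case and control was compared with other splits into 4 and 5, over 100 of the 126 splits with the real one included. The real count past the adjusted threshold was 0, which all 100 splits must reach, so this count says nothing about chance, and the highest in another split was 25. At an unadjusted p, 21 of the 100, the real one included, gave as many probe sets as the real 637, up to 2237 in another split. For lists called, 5 of the 100, the real one included, gave as many as the real 12, up to 13 in another split. Chance cannot be excluded for the count at an unadjusted p or for the number of lists called. The split with 2237, animals 7, 8, 9 and 11 against the rest, points to a structure of the samples that crosses the groups, and these 4 animals lie together on the first principal component.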
